A study of Mus musculus with 12 samples.

How the data were processed

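RNA was sequenced from skeletal muscle of C57BL/6N mice in 12 libraries, 3 in each of 4 groups. Per the labels, mice were 6 weeks old when the diets began and were fed regular chow or a high-fat diet (HFD) for 18 weeks. One HFD group was injected into the peritoneal cavity once a day for 4 days with 50 mg/kg of PCN, and another with the vehicle alone, corn oil holding 30% DMSO. PCN is pregnenolone carbonitrile, a synthetic steroid used in rodents to activate the pregnane X receptor, a nuclear receptor that turns on drug metabolism genes in the liver. Muscle pieces were lysed, total RNA was treated with DNase and Illumina libraries were made, per the labels' protocols. The muscle from which the pieces came is not given in the sources used here. Libraries carry unique numbers, so nothing pairs them, and the labels do not state that each came from a separate mouse. The p-values of single genes measure the spread between these samples.

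The authors deposited 2 tables of raw counts per Ensembl gene, not normalised, with 6 libraries each: HFD with Chow, and PCN with Vehicle. The submitters' processing notes name HISAT2, HTSeq and DESeq2 with the builds GRCm38 and mm10. Versions, the strand setting of the counting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be separated, and reads of near-identical copies (globins, ribosomal proteins with processed pseudogenes, mitochondrial genes with nuclear copies) can be lost or moved between them. The tables held 24093 and 24453 genes, of which 21976 were in both, and each gene kept had a total of at least 1 count over its 6 libraries. For 2117 genes only the HFD and Chow libraries were analysed, 61 of them with a total of 60 or more counts, and for 2477 only the PCN and Vehicle libraries, 4 of them with such a total. Several slow-fibre genes, Myh7 among them, were not analysed here in PCN and Vehicle. The same tables give the authors' own comparison, with mean normalised count, log2 fold change, standard error, statistic, p-value and adjusted p-value. The deposited log2 fold changes lay within 0.02 of a DESeq2 fit with a zero-centred prior for 99.7% of genes in the HFD and Chow table and for 75.9% in the other, so they are pulled towards 0 and are set beside unshrunken values only where named. Symbols came from the tables. For 503 and 523 genes without one, the mouse reference annotation named 493 and 515 by Ensembl identifier. Gene starts and ends matched that annotation, GRCm38, for 97.8% and 97.9% of the identifiers it held. Coordinates below are those of the tables, written 1-based.

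Library totals ran from 12770308 counts (Chow 8) to 19739226 (PCN 27). Within each group, replicate libraries differed by far more than sampling noise, with chi-square values per gene from 21.7 to 121, so each library was counted as 1 sample.

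Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the default expression filter (minimum count 10), robust quasi-likelihood dispersion and the quasi-likelihood F test. The Benjamini-Hochberg adjusted p threshold was 0.05. Log2 fold changes are the first-named group minus the second-named. Standard errors (SE) are the absolute log2 fold change divided by the square root of F, and levels are TMM-normalised counts-per-million values (CPM) with the SD of the 3 libraries. Genes of 38 lists, fixed before the data were examined, were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 where at least 5 members were tested. With that preset value, camera's p compares the genes of a list with other genes. It holds little of the spread between libraries that the members share, which the estimated correlation allows for. Of 828 list members, 802 and 761 matched a gene in the 2 tables. Comparing Vehicle with HFD required joining the tables on the 21976 shared genes. Its gene list results were added after the data were seen. Genes are named by a rule also fixed beforehand. It takes the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean of at least 1 CPM and with groups that do not overlap. Where fewer than 5 genes passed, it takes the 10 with the lowest p instead. Gene models without an assigned name and pseudogenes are counted but not named. The rule also adds up to 4 members with the lowest p of each list described, and Nr1i2, Cyp3a11, Lep, Adipoq, Pdk4, Ucp3, Slc2a4 and Fkbp5. Some genes that the rule takes are not reported here. Genes and libraries singled out outside this rule are said to be so.

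Alternatives were DESeq2 1.42.0, DESeq2 size factors, other expression filters, all 12 libraries in 1 fit, other thresholds, each library left out in turn, and, for lists, an estimated correlation, a preset correlation of 0.05, ranks, and the rotation test fry. The edgeR, DESeq2 and camera steps were tested on simulated counts with known changes. For edgeR and DESeq2, 50 genes each were changed 1.5-fold, 2-fold, 4-fold and 8-fold, and every gene varied independently. With the means and spread of the HFD and Chow libraries, edgeR recovered 62% of genes changed 2-fold and 100% of those changed 4-fold, over 12686 genes. In the same simulation 11.7% of its calls were false. With those of the PCN and Vehicle libraries it recovered 38% and 96%, over 12833 genes, and 14.6% of its calls were false. With those of the HFD and Vehicle libraries it recovered 68% and 90%, over 12746 genes, with 8.22% false. The planted changes ease the adjusted threshold, and the simulation holds no shifts shared between genes. These shares therefore need not hold in the real libraries, where a count of 0 does not exclude 4-fold changes. In HFD against Chow, Mki67 was 6.50-fold higher and did not pass (edgeR adjusted p = 0.255). For a gene with no count in a group, a lower bound of the fold was computed against a floor of 3 counts over that group, which covers counting error only.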

Results

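Gene expression was measured by RNA sequencing of skeletal muscle in 4 groups of 3 libraries: mice on chow (Chow), mice on the high-fat diet (HFD), and HFD mice injected with vehicle (Vehicle) or PCN (PCN). Total counts per library were 12770308 to 18920359 in Chow, 14266093 to 17096576 in HFD, 16790642 to 17628784 in Vehicle and 14379421 to 19739226 in PCN. Mitochondrially encoded genes took 10.8% (HFD 4) to 20.4% (Chow 17) of the counts, and the 10 most abundant genes 37.3% to 47.2%.

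The first comparison asked what the high-fat diet did to the muscle transcriptome. Of the 35 lists tested, 11 passed camera's threshold, 9 lower and 2 higher in HFD, while 0 of 12686 genes passed edgeR's threshold. The lists that fell held genes of the mitochondrial respiratory chain, of the cytosolic ribosome and of slow, oxidative fibres, and the pair that rose held macrophage and cell cycle markers. None of the 11 calls held with an estimated correlation (lowest adjusted p = 0.504).

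All 78 tested nuclear genes of oxidative phosphorylation had lower fitted levels in HFD, with a median log2 fold change of -0.39 (camera adjusted p = 3.33e-21, but adjusted p = 0.760 with an estimated correlation). None passed edgeR's threshold, either over all genes or adjusted over the list alone, and 12 had an unadjusted p under 0.05. Atp5g2, a subunit of ATP synthase (chromosome 15, 102662864 to 102672352), went from 53.0 ± 9.28 CPM in Chow to 33.6 ± 3.18 in HFD (SD, n = 3). Cox6a2, the muscle form of a cytochrome c oxidase subunit, went from 585 ± 142 to 389 ± 26.8 CPM. The list median was -0.18 without Chow 17 and -0.53 without Chow 19. The 13 tested genes of the mitochondrial genome had a median of -0.38 and were all lower (camera adjusted p = 0.000118, with an estimated correlation adjusted p = 0.736; median -0.58 without HFD 30). Among them, mt-Co1 averaged 52152 ± 11749 CPM in Chow and 36282 ± 6264 CPM in HFD. The list of mitochondrial biogenesis and exercise regulators had a median of -0.18, with 14 of 17 lower (camera adjusted p = 0.0280, with an estimated correlation adjusted p = 0.736). Examples were Vegfa (log2 fold change -0.77 ± 0.20, SE) and Perm1 (-0.76 ± 0.23). The fatty acid uptake and oxidation list had a median of -0.12, with 29 of 40 lower (camera adjusted p = 0.00833, with an estimated correlation adjusted p = 0.765). Pdk4, the kinase that restrains pyruvate oxidation, and Acot2, a mitochondrial thioesterase, passed adjusted over the list alone, and 0 members passed over all genes. Pdk4 was at 2846 ± 40.9 CPM in Chow and 1813 ± 195 in HFD, and Acot2 at 40.7 ± 5.17 and 22.5 ± 5.89. Without Chow 17 or without HFD 4 this list's call ended, with medians of 0.048 and 0.031 that lay above 0 while the test's direction stayed downward, and the median was -0.21 without Chow 8, -0.21 without Chow 19 and -0.26 without HFD 38. The call of the biogenesis and exercise regulators ended without Chow 19 (-0.18), HFD 4 (-0.21) or HFD 38 (-0.14).

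Slow-fibre genes had the largest list median, -1.80, with 13 of 14 lower in HFD (camera adjusted p = 3.61e-09, with an estimated correlation adjusted p = 0.736; 0 members passed edgeR's test over all genes or adjusted over the list alone). This difference lay in 2 of the 3 Chow libraries. Myh7, the slow myosin heavy chain (chromosome 14, 54970684 to 54994626), was at 183 CPM in Chow 17 and 312 CPM in Chow 19, but at 2.30 CPM in Chow 8 and at 1.06 to 2.03 CPM in HFD. Myl3, the slow essential light chain, was at 117, 88.8 and 1.53 CPM in Chow 17, 19 and 8 and at 0.152 to 0.214 CPM in HFD, and Tnnt1 (slow troponin T) and Myl2 were likewise high in Chow 17 and Chow 19. The titles number Chow 19 and Chow 17 as 9 and 10, Chow 8 as 1 and the HFD libraries as 4, 5 and 6, so the high slow-fibre levels lay in the 2 highest numbers. With the mean level of the 14 slow-fibre members as a covariate, chosen after the data were seen, 4 lists passed. The oxidative phosphorylation median moved from -0.39 to -0.17 (adjusted p = 0.00368 with the preset correlation, adjusted p = 0.983 with an estimated correlation), and the mitochondrially encoded list no longer passed (-0.082). With Chow 17 and Chow 19 left out together, 3 lists passed, and the oxidative phosphorylation median was -0.26 (adjusted p = 6.04e-11 with the preset correlation), while the slow-fibre list no longer passed (-0.090). In that fit the lone Chow 8 was assumed to vary like the HFD libraries. The fast-fibre list had a median of -0.031 (camera adjusted p = 0.892).

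All 74 tested cytosolic ribosomal protein genes were lower in HFD, with a median of -0.38 (camera adjusted p = 1.71e-26, with an estimated correlation adjusted p = 0.736), 40 of them at an unadjusted p under 0.05. None passed over all genes or adjusted over the list alone. Without Chow 17 the median was -0.24. Rps20 went from 64.6 ± 9.19 to 43.2 ± 1.30 CPM and Rps28 from 49.2 ± 6.88 to 34.3 ± 4.24 CPM. A trend with gene length ran alongside the lists of short genes. Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.257 with exonic length. Its median was -0.12 in the shortest of 5 length groups (median 1.71 kb) and 0.10 in the longest (median 10.1 kb).

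Red blood cell markers had a median of -0.70, with 6 of 6 lower (camera adjusted p = 9.69e-05, with an estimated correlation adjusted p = 0.736), and of -0.38 without Chow 17. Of these, 4 passed adjusted over the list alone and 0 over all genes: Hbb-bs (-0.82 ± 0.27, SE), Alas2, the erythroid heme synthesis enzyme (-0.86 ± 0.32), and the near-identical Hba-a1 and Hba-a2, whose reads the counting could split. The brown or beige adipocyte list had a median of -0.54 with 5 of 6 lower (camera adjusted p = 0.00416, with an estimated correlation adjusted p = 0.504). Its lowest p belonged to Pank1, a coenzyme A synthesis kinase (34.1 ± 3.30 to 20.2 ± 1.78 CPM, the 1 member to pass adjusted over the list alone), Cox8b and Cox7a1, the last 2 also being muscle cytochrome c oxidase subunits. This call ended without HFD 4 (-0.43). The heat shock list had a median of -0.21, with 14 of 16 lower (camera adjusted p = 0.0262, with an estimated correlation adjusted p = 0.765). Its call ended without Chow 17 (-0.12), Chow 19 (-0.31), HFD 4 (-0.16) or HFD 38 (-0.16).

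Macrophage and monocyte markers had a median of 0.38, with 13 of 15 higher in HFD (camera adjusted p = 0.0142, with an estimated correlation adjusted p = 0.765; 0 passed over all genes or adjusted over the list alone). Ctss, a lysosomal protease of myeloid cells, was at 2.72 ± 1.42 CPM in Chow and 6.68 ± 3.62 in HFD, and Laptm5 at 2.84 ± 0.191 and 4.52 ± 1.25. The call rested on single libraries, since the median was -0.013 without HFD 38, the call ended without Chow 19 (0.28), and the median was 0.66 without Chow 8, 0.61 without HFD 4 and 0.60 without HFD 30. Adipocyte markers (median 0.48, 16 of 17 higher) and matrix markers (0.20, 18 of 28 higher) lay on the same side without passing (camera adjusted p = 0.137 and 0.163). HFD 38 had the highest adipocyte and matrix scores of the 6 libraries, 4.72 and 5.68 (mean log2 CPM). The cell cycle list passed with only 4 of 7 members higher (median 0.32, camera adjusted p = 0.00590, with an estimated correlation adjusted p = 0.504), and its call ended without Chow 19 (0.14), with a median of 0.16 without Chow 8. It was carried by 2 genes that passed adjusted over the list alone, with 0 over all genes. Mki67, a proliferation marker (chromosome 7, 135689784 to 135716361), was at 0.537 ± 0.191 CPM in Chow and 3.58 ± 1.67 in HFD (log2 fold change 2.70 ± 0.44, SE). Top2a, a topoisomerase of dividing cells, had a log2 fold change of 2.82 ± 0.55.

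**Figure D1:**
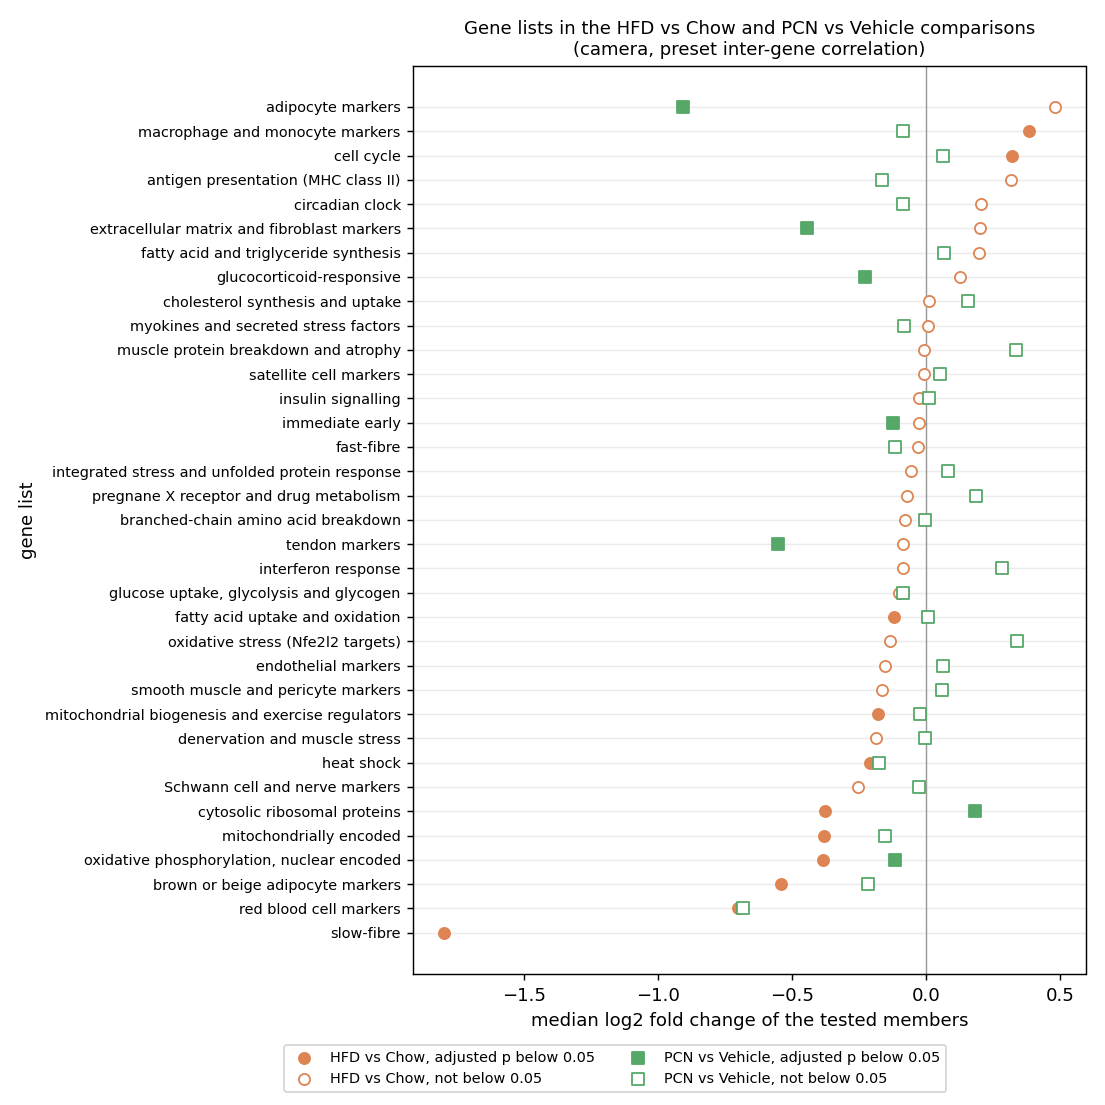
Median log2 fold change of the tested members of each gene list (x axis, log2 units; y axis, list) for HFD vs Chow (circles) and PCN vs Vehicle (squares), filled where camera's adjusted p with the preset correlation was below 0.05. The slow-fibre list lies lowest for HFD vs Chow at -1.80 and the adipocyte list lowest for PCN vs Vehicle at -0.91, and no filled point stayed below 0.05 with an estimated correlation.

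No gene passed edgeR's threshold in HFD against Chow (0 of 12686, lowest adjusted p = 0.241), and 977 had an unadjusted p under 0.05, 480 higher and 497 lower, against 634 expected by chance. DESeq2 called 40 (21 higher, 19 lower), and the authors' deposited table called 27 (16 higher, 11 lower), all among DESeq2's 40 and of the same sign in edgeR. Groups did not overlap for 12.8% of genes, against 10% by chance. The genes with the lowest p did not pass and were the following. Asb15, a muscle ubiquitin ligase adaptor (chromosome 6, 24528144 to 24573164), was at 38.8 ± 4.06 CPM in Chow and 87.7 ± 18.6 in HFD (log2 fold change 1.17 ± 0.17, SE). Mdga1, a cell surface glycoprotein (chromosome 17, 29827949 to 29970087), was at 5.43 ± 0.941 and 12.7 ± 1.72 CPM. Gabarapl1, an autophagosome protein (chromosome 6, 129533160 to 129542346), was at 89.0 ± 10.4 and 48.7 ± 2.48 CPM (-0.87 ± 0.13). The others higher in HFD were the phosphatase Cdc14a (0.84 ± 0.13), the cadherin Fat3 (1.60 ± 0.27), Stxbp4 (0.76 ± 0.13) and Cep85l (0.80 ± 0.14), besides Mki67. The complement component C7 was lower (-1.25 ± 0.23). Itgad, an integrin chain of macrophages, had 0 counts in all 3 Chow libraries and 78 in HFD, at least 26.9-fold higher against a floor of 3 counts over the Chow group. Without Chow 19, edgeR called 219 genes, without Chow 8 it called 7, and with no expression filter 237.

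Other genes given irrespective of their result did not pass. Fkbp5, a glucocorticoid target, had a log2 fold change of 0.42 ± 0.14 (SE). Slc2a4, which encodes the insulin-responsive glucose transporter, was at -0.19 ± 0.13 and Ucp3 at -0.13 ± 0.14. Lep (1.35 ± 1.24) and Adipoq (0.53 ± 1.26), made by adipocytes, varied between libraries. Adipoq spanned 0.858 to 33.2 CPM within Chow, and its sign turned without Chow 19 (-0.058) and without HFD 38 (-0.47). The hepatic PXR target Cyp3a11 had at most 1 count in any Chow or HFD library, too few to test, and Nr1i2, which encodes PXR, was not analysed here.

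**Figure D2:**
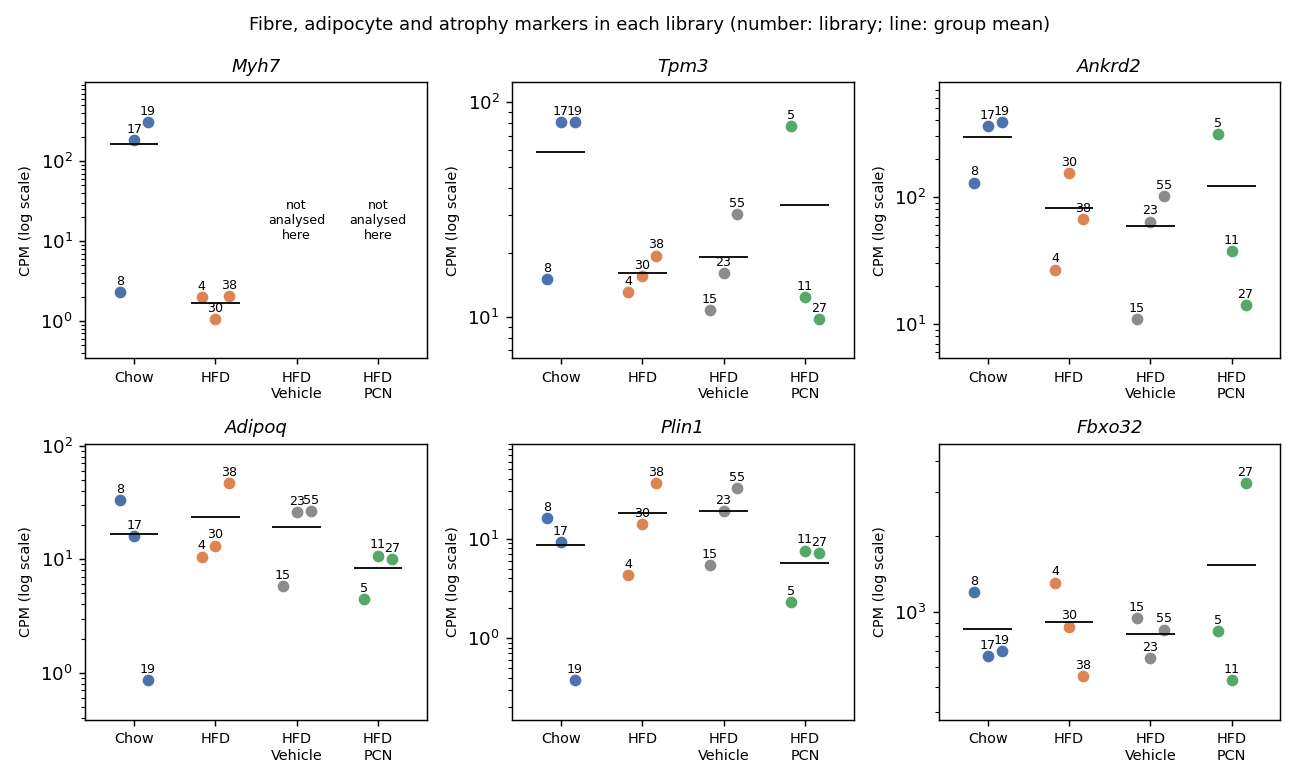
CPM on a log scale (y axis) of slow-fibre (Myh7, Tpm3, Ankrd2), adipocyte (Adipoq, Plin1) and atrophy (Fbxo32) genes in each library, with points numbered by library and lines at group means; groups are on the x axis, values are normalised within each table, and Myh7 was analysed in Chow and HFD only. Myh7 was at 183 and 312 CPM in Chow 17 and Chow 19 and at 1.06 to 2.30 CPM in the other 4 libraries, and Fbxo32 at 3252 CPM in PCN 27.

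The next comparison asked what 4 days of PCN did to the muscle of HFD mice. As lists, connective tissue and fat cell genes were lower in PCN than in Vehicle and ribosomal protein genes slightly higher, while no gene changed past the threshold. Of 34 lists tested, 7 passed camera's threshold, 6 lower and 1 higher. None held with an estimated correlation (lowest adjusted p = 0.449). The pregnane X receptor and drug metabolism list did not pass (11 members tested, 8 higher, median 0.19, camera adjusted p = 0.249). Of its 38 genes, only 18 were analysed in PCN and Vehicle. The hepatic PXR target Cyp3a11 was not analysed in these libraries. A response of the genes left out could not be seen.

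Extracellular matrix and fibroblast markers had a median log2 fold change of -0.44, with 23 of 25 lower in PCN (camera adjusted p = 3.65e-11, with an estimated correlation adjusted p = 0.916). Dpt, a dermatopontin found in connective tissue matrix, was at 24.1 ± 2.59 CPM in Vehicle and 14.7 ± 4.84 in PCN (SD, n = 3), and Sparc at 92.8 ± 18.9 and 63.8 ± 13.8. The list median was -0.77 without PCN 11 and -0.26 without PCN 27. Tendon markers had a median of -0.55, with 6 of 6 lower (camera adjusted p = 0.000289, with an estimated correlation adjusted p = 0.449), among them Col12a1 (-0.53 ± 0.20, SE) and Thbs4 (-0.58 ± 0.23). Adipocyte markers had a median of -0.91, with 16 of 17 lower (camera adjusted p = 5.00e-09, with an estimated correlation adjusted p = 0.916). The lipid droplet protein Plin1 was at 18.9 ± 13.3 CPM in Vehicle and 5.70 ± 2.95 in PCN, Nnat at 10.9 ± 6.33 and 3.32 ± 2.59, and Slc7a10 at 2.24 ± 1.05 and 0.939 ± 0.289. Vehicle 15, at 5.47 CPM of Plin1, lay within the PCN range of 2.30 to 7.61. Without PCN 11 the adipocyte median was -1.40. In these 3 lists 0 members passed over all genes or adjusted over the list alone. With PCN 5 and PCN 27 left out together, chosen after the data were seen, the matrix list no longer passed (-0.030), while the adipocyte (-0.85) and tendon (-1.01) lists did. The lone PCN 11 was there assumed to vary like the Vehicle libraries.

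Ribosomal protein genes had a median of 0.18, with 73 of 74 higher in PCN (camera adjusted p = 7.60e-08, with an estimated correlation adjusted p = 0.932), and the call ended without Vehicle 55 (0.073), with a median of 0.089 without PCN 11. Rps27 was at 88.2 ± 9.77 CPM in Vehicle and 113 ± 6.80 in PCN. Nuclear oxidative phosphorylation genes had a median of -0.11, with 73 of 78 lower (camera adjusted p = 0.000737, with an estimated correlation adjusted p = 0.932), and this turned to 0.045 without PCN 27 and lost its call without Vehicle 55 (-0.028), with -0.28 without PCN 5 and -0.20 without Vehicle 15. Examples were Ndufs4 (-0.28 ± 0.17, SE) and Atp5g3 (-0.43 ± 0.28). Slow-fibre levels also varied between these libraries. The mean log2 CPM of the 5 slow-fibre members analysed in all libraries was 4.37 in PCN 5, 1.62 in PCN 11 and 1.30 in PCN 27. In Vehicle it ran from 1.39 to 3.39. Glucocorticoid-responsive genes had a median of -0.23, with 21 of 25 lower (camera adjusted p = 0.00277, with an estimated correlation adjusted p = 0.916), a call that ended without Vehicle 15 (-0.11). Fkbp5 was at 104 ± 5.27 CPM in Vehicle and 82.1 ± 4.62 in PCN, and the transcription factor Zbtb16 had a log2 fold change of -0.32 ± 0.17 (SE). Immediate early genes had a median of -0.12, with 14 of 22 lower (camera adjusted p = 0.0206, with an estimated correlation adjusted p = 0.916), and the call ended without PCN 27 (-0.025) or Vehicle 15 (-0.13), with -0.34 without PCN 5, -0.25 without PCN 11 and -0.19 without Vehicle 23. Nr4a1 (-0.72 ± 0.22) and Myc (0.43 ± 0.17) lay on opposite sides of 0. With the title numbers up to 7 and above 7 as a block, chosen after the data were seen, the glucocorticoid call ended (-0.15) and the immediate early median was -0.21. None of the members of these 4 lists passed over all genes or adjusted over the list alone.

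By edgeR, 0 of 12833 genes passed (lowest adjusted p = 0.998), and 362 had an unadjusted p under 0.05, 173 higher and 189 lower, against 642 expected by chance. DESeq2 called 0, and the authors' deposited table called 0 (lowest adjusted p = 0.1945). Groups did not overlap for 8.48% of genes, against 10% by chance. The lowest p, not passing, belonged to Kcnq5, a potassium channel (chromosome 1, 21398403 to 21961942; 34.9 ± 7.65 CPM in Vehicle, 17.1 ± 1.38 in PCN). The other genes named by the fixed rule were Fras1 (-1.76 ± 0.34, SE), Tigd4 (-1.34 ± 0.28), Ifitm10 (-2.20 ± 0.53), the kinase Sik1 (-0.69 ± 0.17) and the cytokine signalling inhibitor Cish (-1.35 ± 0.33). Trdn, triadin of the calcium release complex (chromosome 10, 33080554 to 33476709), was at 1245 ± 305 CPM in Vehicle and 558 ± 176 in PCN. Cldn1 (1.71 ± 0.43) was higher, and Map3k7cl (-1.54 ± 0.39) and Ptger3 (-1.43 ± 0.37) were lower. Among the 12 genes of lowest p, 2 gene models without an assigned name, which the rule leaves out, were both higher in PCN. With no expression filter, edgeR called 21 genes. Pdk4 was at 1344 ± 274 and 1347 ± 250 CPM, Slc2a4 at 273 ± 31.4 and 243 ± 36.2, Ucp3 at 317 ± 14.6 and 293 ± 46.9, Lep at 28.5 ± 14.6 and 12.4 ± 6.39, and Adipoq at 19.4 ± 11.8 and 8.39 ± 3.43, in Vehicle and PCN.

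Whether PCN moved genes in the direction of the diet or against it was examined over 12398 genes tested in both comparisons, which share no library. The log2 fold changes had a Pearson r of -0.18 and a Spearman rho of -0.14 across genes, which are not independent replicates. The jackknife SD over libraries was 0.134, and r ran from -0.20 to -0.078 with each library left out, the values closest to 0 being those without PCN 5 (-0.078), HFD 38 (-0.084) and Chow 19 (-0.11). Past the threshold in both there were 0 genes. Among genes at an unadjusted p under 0.05, 18 were higher in HFD and lower in PCN where 6.77 were expected, Fkbp5, Fras1 and Cep85l among them. Another 10 genes were lower in HFD and higher in PCN (6.03 expected), 3 higher in both (5.86) and 4 lower in both (6.96). Genes are not independent, so these counts are given without a p. Over the 35 genes at that p in both comparisons, r was -0.70. These are the genes just counted, chosen by their changes in both, so this r restates the counts and adds no evidence.

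Vehicle and HFD mice were both on the high-fat diet and differed by the injections. Their libraries were held in different tables, and a difference in handling between these is not given in the sources used here. The titles number the HFD libraries 4, 5 and 6, and the Vehicle libraries 3, 8 and 11. The same HFD libraries also served in HFD against Chow, and the same Vehicle libraries in PCN against Vehicle. A trait of the HFD libraries alone would appear in both of their comparisons with opposite sign. Changes that mirror those of HFD against Chow are therefore not separate results. Of 12746 genes tested among those shared by the tables, 193 changed past edgeR's threshold, 67 higher and 126 lower in Vehicle, and 2273 had an unadjusted p under 0.05. Groups did not overlap for 23.5% of genes, against 10% by chance. DESeq2 called 607, of which 184 were shared with edgeR.

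Among the largest rises in Vehicle were Klf10, a TGF-beta-responsive transcription factor (19.1 ± 6.63 CPM in HFD, 42.4 ± 6.49 in Vehicle, adjusted p = 0.0499), Gpx3, the secreted glutathione peroxidase (55.8 ± 13.5 and 116 ± 22.2, adjusted p = 0.0452), Mid1ip1 and Impdh2. Polr1has and Nop10 (log2 fold change 0.93 ± 0.13, SE) rose too, as did Atp5g2 (0.89 ± 0.14) and the ribosomal protein genes Rps27, Rpl37a, Rpl7a and Rps28 (0.78 to 0.88). The largest falls included Atp1b2, a sodium pump subunit (chromosome 11, 69599736 to 69605942; 72.1 ± 14.1 CPM in HFD, 21.9 ± 4.71 in Vehicle, adjusted p = 0.0113). Mki67 fell by 2.29 and Pcdh12 by 2.29 on the log2 scale, the presynaptic gene Pclo by 2.23 and Tlcd3b by 1.87. Falls were also seen in the chloride channel gene Best3 (-1.77 ± 0.21), Zfhx2 (-1.75 ± 0.32), the kinases Mast4 (-1.60 ± 0.21) and Hipk2 (-1.54 ± 0.22), Mdga1 (-1.53 ± 0.17) and the transcription factor Maff (-1.50 ± 0.18). Over all 4 groups, Mki67 averaged 0.571 CPM in Chow, 3.75 in HFD, 0.770 in Vehicle and 0.822 in PCN, and Mdga1 5.77, 13.4, 4.64 and 2.36 CPM.

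The count of calls rested on single libraries. It was 0 without HFD 30 or Vehicle 23, 9 without Vehicle 15, 14 without HFD 4, 48 without HFD 38 and 1180 without Vehicle 55. A trend with gene length ran alongside, with a Spearman rho of -0.31 across genes and medians from 0.18 in the shortest to -0.15 in the longest of 5 length groups. Pdk4 (-0.58 ± 0.20, SE), Fkbp5 (-0.033 ± 0.14), Slc2a4 (0.065 ± 0.14), Ucp3 (-0.077 ± 0.13), Lep (-0.54 ± 0.75) and Adipoq (-0.43 ± 0.84) did not pass.

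**Figure D3:**
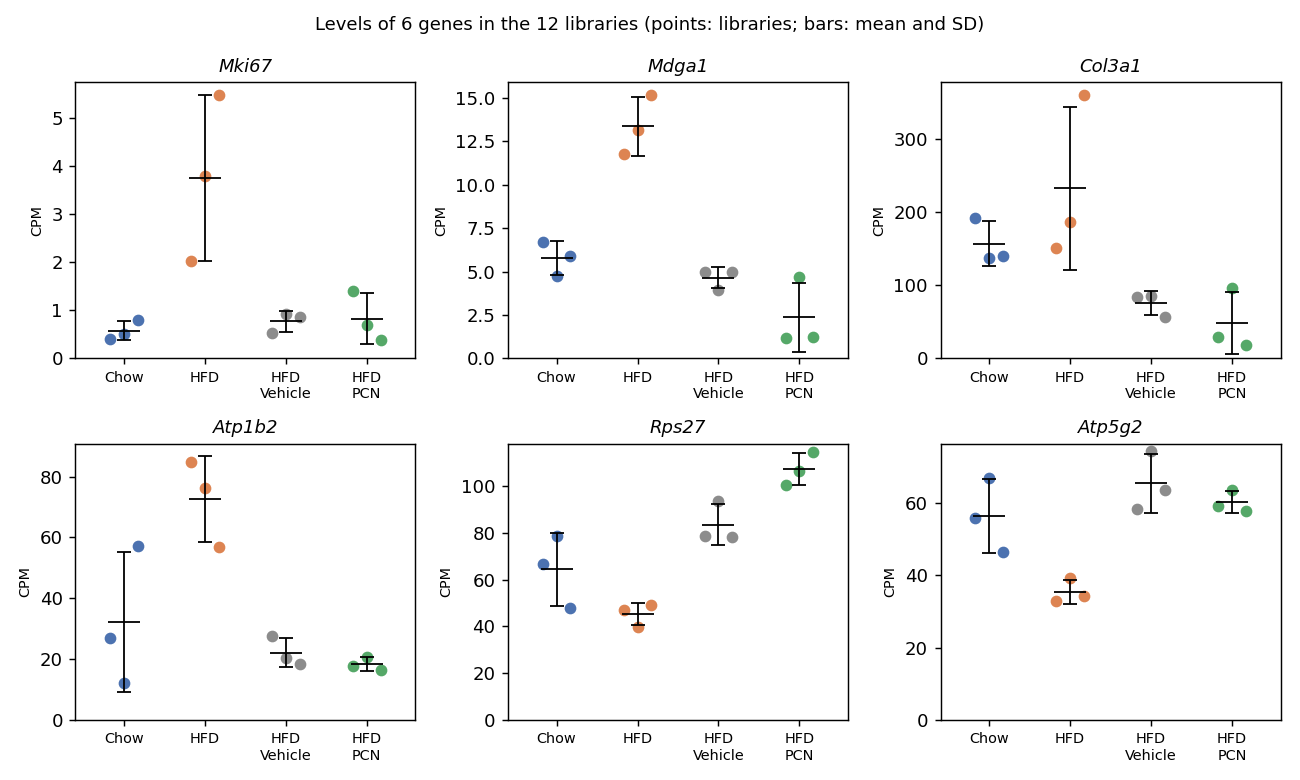
Levels in CPM (y axis, from 0) of 6 genes in the 4 groups (x axis), normalised over the 12 libraries; points are libraries and bars the mean and SD of 3. Mki67 and Mdga1 averaged 3.75 and 13.4 CPM in HFD, above the other 3 groups, and Atp5g2 averaged 35.4 CPM in HFD, below them.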

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

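The covariates, the block of title numbers, the paired omissions, and the alternatives for the Vehicle vs HFD lists were chosen after the data were seen. Causes of the shifts were not tested. For HFD vs Chow, edgeR's count of 0 genes became 40 with DESeq2 and 237 with no expression filter, 0 to 219 with a library left out, and stayed 0 under the other settings. For PCN vs Vehicle it became 21 with no filter and was 0 otherwise. For Vehicle vs HFD, 193 became 607 with DESeq2 and 0 to 1180 with a library left out. The 11 lists of HFD vs Chow became 0 with an estimated correlation, 1 with fry (cell cycle, adjusted p = 0.0133), 0 with fry's mixed test, 7 with a preset correlation of 0.05, 4 with the slow-fibre covariate, 0 with that covariate and an estimated correlation, 3 without Chow 17 and Chow 19, and 10 to 18 with a library left out (18 without Chow 8). The 7 lists of PCN vs Vehicle became 0 with an estimated correlation, 0 with fry, 0 with its mixed test, 4 with a preset correlation of 0.05, 11 with an adipocyte covariate, 11 with the title numbers as a block, 0 with that block and an estimated correlation, and 8 to 13 with a library left out (12 without PCN 5, 13 without PCN 11, 11 without Vehicle 55). The 6 lists of Vehicle vs HFD became 0 with an estimated correlation, 0 with fry, 14 with its mixed test, and 6 to 11 with a library left out (10 without HFD 38, 11 without Vehicle 15, 10 without Vehicle 23). The correlation of the HFD and PCN changes moved from -0.18 to -0.70 over genes at an unadjusted p under 0.05 in both, which are chosen by those same changes. In HFD vs Chow the slow-fibre covariate turned the sign of Adipoq (-0.18), mt-Nd6 (0.022), Esrrg (0.34), Hsp90aa1 (0.057), Cryab (0.17), the fatty acid oxidation list (0.19) and the heat shock list (0.11). Leaving out Chow 17 and Chow 19 turned Adipoq (-0.50), Esrrg (0.066) and the heat shock list (0.027). With single libraries left out, Ppargc1a ran from -0.79 to 0.12, Adipoq from -0.47 to 1.51 and the macrophage list from -0.013 to 0.66. In PCN vs Vehicle, Pdk4 turned with no filter (-0.0050), with all 12 libraries (-0.0012), with the block (-0.15) and without PCN 5 and PCN 27 (-0.31), as did Slc2a4 (0.041) and Ucp3 (0.11) in the last. The adipocyte covariate turned Adipoq (0.090), Ndufa11 (0.030) and Comp (0.053). With single libraries left out, Pdk4 ran from -0.13 to 0.17, Comp from -1.77 to 0.14 and the oxidative phosphorylation list from -0.28 to 0.045. In Vehicle vs HFD, Fkbp5 ran from -0.10 to 0.086, Lep from -0.88 to 0.39 and Adipoq from -0.77 to 0.55. Of the values of named genes with a library left out, 325 of 348 in HFD vs Chow, 253 of 258 in PCN vs Vehicle and 165 of 288 in Vehicle vs HFD kept their direction and side of the threshold, and 110 of the last fell short of it. Under the other settings 464 of 515, 414 of 428 and 32 of 48 did. Settings written for files with normalised values or comparison columns alone (pseudocounts, low-value filters, base mean filters and readjusted p-values) were not run, since counts were held. No paired analysis was possible because library numbers are unique. At totals of 12770308 to 19739226 counts, the simulated recovery of 2-fold changes was 38% for PCN vs Vehicle, so changes of that size could not be excluded. Larger changes were not excluded either, since the simulated genes varied independently.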

Other observations

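Tests chosen only after the result was seen were the leave-one-out bound and the covariate test for the oxidative phosphorylation list, the count of Chow libraries with high slow-fibre levels, the share of liver genes highest in PCN 5, the splits of the overlap, the block of title numbers, the score differences with their errors, the reading of each bound against the spread between libraries, and all list tests of Vehicle against HFD.

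Vehicle muscle differed from uninjected HFD muscle in 6 of 35 lists, 2 higher and 4 lower, with none held under an estimated correlation (lowest adjusted p = 0.783). All 74 ribosomal protein genes were higher in Vehicle, with a median log2 fold change of 0.62 (camera adjusted p = 1.32e-57, with an estimated correlation adjusted p = 0.783), 32 past edgeR's threshold over all genes and 72 adjusted over the list alone. Nuclear oxidative phosphorylation genes had a median of 0.27, with 72 of 78 higher (camera adjusted p = 1.13e-10, with an estimated correlation adjusted p = 0.999). Both lists were lower in HFD than in Chow, in the same HFD libraries, so these shifts are not independent of those. Ribosomal scores (mean log2 CPM) were 5.67 to 5.78 in HFD, 5.77 to 6.35 in Chow and 6.12 to 6.45 in Vehicle. Extracellular matrix and fibroblast markers had a median of -0.77, with 23 of 25 lower (camera adjusted p = 1.04e-12, with an estimated correlation adjusted p = 0.915), 1 past the threshold over all genes and 14 adjusted over the list alone. Among them Col1a1 fell by 1.32 and Col3a1, which did not pass over all genes, was at 231 ± 111 CPM in HFD and 75.0 ± 15.9 in Vehicle (SD, n = 3). Tendon markers (median -0.71, camera adjusted p = 0.000585, with an estimated correlation adjusted p = 0.843) and immediate early genes (-0.38, camera adjusted p = 0.00175, with an estimated correlation adjusted p = 0.915) were lower. The cell cycle list (-0.21, camera adjusted p = 0.0308, with an estimated correlation adjusted p = 0.783) was carried by Mki67 and Top2a. The immediate early and cell cycle calls ended without Vehicle 55 (-0.46 and -0.17). Other medians moved by over 1.5 times without 1 library: oxidative phosphorylation without HFD 4 (0.17) or Vehicle 55 (0.17), matrix without HFD 38 (-0.42), tendon without Vehicle 23 (-0.47), immediate early without HFD 4 (-0.24) or HFD 38 (-0.58), and cell cycle without Vehicle 23 (-0.37).

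The circadian clock list did not pass in HFD against Chow (camera adjusted p = 0.150), but 3 members, named here after their values were seen, passed adjusted over the list alone and 0 over all genes. Arntl, the activator of the clock, was at 33.3 ± 5.62 CPM in Chow and 21.2 ± 3.97 in HFD (SD, n = 3), and the repressors Per2 and Per3 had log2 fold changes of 0.73 ± 0.21 and 0.67 ± 0.17 (SE). PCN 27, singled out after its values were seen, held the ubiquitin ligase gene Fbxo32 at 3252 CPM, against 533 to 940 CPM in the other 5 libraries of its table. It also held Trim63 at 1349 CPM, against 299 to 637. In Chow and HFD, normalised apart, Trim63 ran from 493 CPM (Chow 17) to 1236 CPM (Chow 8).

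The oxidative phosphorylation list had a lower median in HFD than in Chow. Its score differed by -0.35 ± 0.22 (SE), with a 95% interval of -0.97 to 0.27 from the spread between libraries. A lack of difference was thus not excluded, and HFD 38 (6.74) scored above Chow 19 (6.64). In these libraries the list lay below genes of the same exonic length (difference -0.29, 95% bootstrap interval -0.32 to -0.25 over 1000 resamples of genes, which are not independent). This argues against a length trend as the whole shift in these libraries only. The interval holds no spread between libraries, so it does not settle the question beyond them. A different fibre make-up of the muscle pieces may account for the shift. Within groups, the slow-fibre score, from the 5 members analysed in all libraries, and the oxidative phosphorylation score had a Pearson r of 0.64 over 12 libraries (exact permutation p = 0.0841 over 1296 permutations; Spearman rho 0.65, exact permutation p = 0.0563). This r was above the bound of 0.5 set beforehand, but with a permutation p above 0.05. It rested partly on PCN 5 and PCN 27 (0.44 without them). Within Chow the scores did not go together throughout. Chow 17 was high in both (4.14 and 7.30). Chow 19 had the highest slow-fibre score (4.38) but the lowest oxidative phosphorylation score (6.64), below Chow 8 (2.94 and 6.83). Without Chow 19 the list median was -0.53. Whether fibre make-up accounts for all of the shift stays open. The list's score differed by -0.24 ± 0.29 (SE) with the slow-fibre score of the 5 members as a covariate. It differed by -0.16 ± 0.36 (SE) with the score of the 14 members tested in Chow and HFD (list median from -0.39 to -0.17). The weight of 1 library stays open too, with a median of -0.18 and a score difference of -0.17 ± 0.17 (SE) without Chow 17. An effect of diet on the oxidative phosphorylation list was not tested apart from these and stays open. For the slow-fibre list, the scores of the 14 members were above every HFD library in 2 of the 3 Chow libraries. Chow 8 (3.18) lay within the HFD range of 1.88 to 3.21, which met the bound written against an effect shared by all Chow libraries. Since Chow 8 alone met it, an effect of diet on slow-fibre genes was left open too. The Vehicle libraries were also on the high-fat diet. Their oxidative phosphorylation scores were 6.65 to 7.02, against 6.64 to 7.30 in Chow and 6.36 to 6.74 in HFD. The lower level was thus not seen in all libraries on that diet. Vehicle and HFD also differed by the injections, so these scores cannot settle a diet effect.

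Adipocyte markers were lower in PCN than in Vehicle. A varying amount of adipose tissue in the muscle pieces may account for it, since 9 markers moved together within groups, with a mean pairwise Pearson r of 0.80 over 36 pairs, and Vehicle 15 lay within the PCN range. The list median was -0.69 without PCN 27, the closest to 0 of the 6 omissions and past the bound of -0.3 set beforehand. The list's score then differed by -0.79 ± 0.73 (SE), hardly moved from -0.79 ± 0.56 with all libraries. The error was wide with and without PCN 27, so the weight of 1 library stays open. An effect of PCN on fat cells stays open and was not tested apart from these.

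PCN 5 held liver-expressed transcripts at higher counts than the other libraries of its table. Of 80 liver genes listed before this test, 8 were analysed in PCN and Vehicle, and 100% of these had their highest count in PCN 5, among them Nr1h4 (80 counts, at most 13 elsewhere) and Keg1 (24, at most 4). Liver RNA in that library may be the source, but kidney also expresses several of these genes, and the most abundant liver transcripts were not analysed here. Induction by PCN in muscle stays open: the summed CPM of these genes in PCN 11 and PCN 27 was 0.994 times that in Vehicle, below the bound of 1.2 set beforehand, but the upper 95% limit of this ratio from the spread between libraries was 2.64.

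Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. Where the real count is 0, every split is as large by definition, so 10 of 10 tells nothing there. HFD against Chow gave 977 genes at an unadjusted p under 0.05, with a highest other split of 1941 (2 of 10 splits as large), 0 genes past the threshold, with a highest other of 1 (10 of 10), and 11 lists, with a highest other of 17 (8 of 10). PCN against Vehicle gave 362 genes at that p, with a highest other of 2221 (6 of 10), 0 past the threshold, with a highest other of 279 (10 of 10), and 7 lists, with a highest other of 19 (10 of 10). The split that called 279 genes, the highest of the 10, set PCN 5, PCN 27 and Vehicle 55, numbered 2, 7 and 3 in the titles, against the libraries numbered 8, 11 and 12. A structure of the samples may lie behind so many calls, but the split was picked for its count and no separate test was run. What the title numbers mark is not given in the sources used here. Matrix scores, looked at after the split was picked, also separated the 2 sets (3.56 to 4.26 against 4.32 to 4.54). With the sets as a block, 11 lists passed with the preset correlation and 0 with an estimated correlation, and the matrix median was -0.40. In the other comparisons the numbers above 7 belong to 1 group only, which leaves Chow 8 or Vehicle 55 alone to set against HFD among the lower numbers. Vehicle against HFD gave 2273 genes at that p, with a highest other of 1514 (1 of 10), 193 past the threshold, with a highest other of 0 (1 of 10), and 6 lists, with a highest other of 18 (10 of 10). For the correlation of the HFD and PCN changes, 20 of 100 pairs of splits gave an absolute r as large as the real one, with a highest other of 0.403, so chance is not excluded. For the overlap of genes higher in HFD and lower in PCN, 40 of 100 pairs gave as low a Fisher p in some direction, the lowest other being 8.89e-56, so chance is not excluded there either.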
